A study of Mus musculus with 6 samples.

How the data were processed

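Poly(A) RNA sequencing libraries of 6 mouse cell samples were analysed, 3 labelled female germline stem cells (FGSC) and 3 labelled differentiated female germline stem cells (Dif-FGSC). Per the labels' protocols, RNA was extracted with Trizol and libraries were made with a KAPA stranded mRNA kit. The authors deposited a table of FPKM values (fragments per kilobase of transcript per M mapped fragments, where M stands for mega) with a row per gene symbol and a column per library. HISAT2 4.8.2 and Cufflinks 2.2.1 are named in the submitters' processing notes together with the mouse build mm9, without saying which step each performed. The gene annotation and the strand setting used for counting are not given in the sources used here, so values of overlapping, antisense or near-identical genes are uncertain. The table's columns carry the prefixes con and dif. The prefix con was read as control and assigned to FGSC, which is a reading of the name and not a statement in the labels, and every direction given rests on it. No coordinates are given, because the supplied reference annotation is of another build.

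The table held 24674 rows. Of these, 26 symbols had the form of a calendar date, as spreadsheet programs produce, and were kept as they stood. For each of 2 duplicated symbols the row with the higher mean was kept, and 1 value outside the named columns was ignored, leaving 24672 genes. Of these symbols, 24564 matched the supplied reference gene names. In all 6 libraries 10035 genes were listed at 0.

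Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(FPKM + 1), for the 9162 genes whose mean over the 6 libraries was at least 1 FPKM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 differences are on the log2(FPKM + 1) scale, which understates the change of low genes. They are given as Dif-FGSC minus FGSC with the standard error from the moderated fit, while ± after an FPKM value is the SD of 3 libraries. An FPKM table does not carry counts, so no count model was used. With 3 libraries against 3, an exact two-sided permutation test of a single gene cannot give a p below 0.1. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

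Gene lists for 23 pathways, complexes and cell types, with 649 symbols in all, were fixed before the data were examined, as were the main test, its filter and pseudocount, most of the alternative analyses and the rule for naming genes. The 15 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the lists. The genes named were the 8 largest rises and 8 largest falls among called genes with non-overlapping groups and a mean of at least 5 FPKM in the higher group, 15 markers fixed in advance, and the called members with the largest log2 differences of each list. Up to 4 members came from each of the germline, meiosis, retinoic acid, chromatin architecture, granulosa and fibroblast lists, and up to 2 from each other list. Predicted genes and small RNAs were left out of the largest changes. Because many of the largest changes involved genes listed at exactly 0, the same rule was also run without such genes, a choice made after the data were seen. Genes named outside these rules were chosen after their values were seen, namely Ptprc, Id2, Itga6, Tet3, Crebbp, Hdac2, Junb, Fosl1, Dusp5, Etv4, Spry1, Dusp6, Spry4, Spred1, Spred2, Tgm2, Nqo1, Pgk1, Eno1, Hk1, Foxm1, E2f1, Cdkn1b, Hmox1, Gclm, Prdm9, Tex14, Rpl30 and those of the added lists, with Trap1a. The BMP genes Id1, Id3, Smad7, Hey1 and Bambi were likewise named after their values were seen. A value listed at 0 can be a failed estimate, so such genes are given per library and without a fold.

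Depth was estimated from the steps between low FPKM values of 6024 genes with a single annotated transcript in the reference. Between 68.2% and 69.8% of those low values per library lay within 0.1 of a whole number of fragments, where chance gives 20% for a step fixed in advance. The step was set from these same values, which raises the share. The numbers of fragments given for single genes use the longest reference transcript, are approximate and cover counting error only. The detection floor of a library was set at 3 fragments, which for a transcript of 2000 bp is 0.055 to 0.086 FPKM.

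The limma script was tested on simulated libraries with 200 of 9162 genes changed. The changed genes were drawn from those at about 5 FPKM or more, and the simulated noise was normally distributed. Recovery of lower genes was not measured. Of 50 genes changed 1.2-fold it recovered 39 (78%), and it recovered all 50 genes at each of 1.5-fold, 2-fold and 4-fold. It made 11 false calls among 8962 unchanged genes. The data called 5965 genes, far more than the 200 changed in the simulation. The cut on the unadjusted p depends on the share of changed genes, so these rates need not hold for the data. Each library was counted as its own sample, as the labels list it. Replicates of a group differed by more than sampling noise (mean chi-square per gene of 1.64 to 4.41 within groups), which can also arise between repeat libraries of a single culture. The alternatives were pseudocounts of 0.1 and 0.01, no filter on low values or a filter at 5 FPKM, median-ratio scaling, quantile normalization, other variance models, a block by replicate number, each library left out in turn, predicted genes left out, and, chosen after the data were seen, genes listed at 0 in any library left out. List tests were repeated with an estimated inter-gene correlation and with fry. Tables and figures were made with Python 3.11.15, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.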

Results

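RNA sequencing was used to compare cultured mouse female germline stem cells (FGSC), proliferating cells derived from the ovary that are described as able to form oocytes, with the same cells after induction of differentiation (Dif-FGSC). The series title sets the question of how retinoic acid starts meiosis in these cells and how chromatin structure changes with it. Each group had 3 libraries from C57BL/6 cells of late passage. FGSC were grown on inactivated STO fibroblasts with the growth factors LIF, EGF, bFGF and GDNF. Dif-FGSC were moved to inactivated granulosa cells in medium with bFGF, 10 ng/mL BMP4 and 0.1 µmol/L retinoic acid, so the feeder cells and the growth factors differed between the groups together with retinoic acid. The low FPKM values implied 27.3, 21.9 and 17.4 M fragments in the libraries labelled FGSC and 22.6, 19.6 and 19.8 M in those labelled Dif-FGSC. Between 12388 and 12830 genes per library had a value above 0. Across genes, Pearson correlations of log2(FPKM + 1) were 0.9936 to 0.9963 within groups and 0.9625 to 0.968 between groups, and genes are not independent replicates.

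Most genes that mark germ cells were at or near 0 in all 6 libraries. Ddx4, a germ cell RNA helicase, did not exceed 0.0104 FPKM, an estimated 0.5 fragments, and Dazl, a germ cell RNA-binding protein, and Gfra1, the receptor for GDNF, were listed at 0 in every library. Sycp3, a core protein of the synaptonemal complex, and Dmc1, the meiotic recombinase, were also listed at 0 in every library, and Pou5f1, a pluripotency factor, did not exceed 0.0446 FPKM. For Sycp3 the floor of 3 fragments allows up to 0.147 FPKM in the shallowest library, and for Ddx4 up to 0.057. Of 29 germline genes in the table, 19 stayed below 0.1 FPKM in every library. The same held for 29 of 48 meiosis genes, 22 of 26 pluripotency genes and 22 of 26 oocyte genes. Some members stood higher, among them the meiosis genes Prdm9 and Tex14. Prdm9 stood at 1.557 FPKM in libraries labelled FGSC and 1.322 in those labelled Dif-FGSC, and Tex14 at 1.915 and 2.13. None of 116 broadly used genes (proteasome, chaperonin and mitochondrial ribosome subunits) was listed at 0 in any library. Other broadly used genes were listed at 0 in some libraries, among them the chaperone gene Hspa8 and the ribosomal protein gene Rpl30. Since the low germ cell markers go against the cell type named in the labels, directions below are stated for libraries labelled FGSC and Dif-FGSC.

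Several transcripts of blood cells were abundant in both groups. Ptprc, the pan-leukocyte phosphatase CD45, stood at 14.0 ± 0.701 FPKM in libraries labelled FGSC and 17.6 ± 0.544 in those labelled Dif-FGSC. Laptm5, a lysosomal protein of blood cells, stood at 99.8 ± 4.83 and 187 ± 4.59 FPKM. Gata2, a transcription factor of blood progenitors that was listed under BMP response, stood at 185 ± 1.57 and 248 ± 6.98 FPKM. Of 17 immune genes in the table, 7 stayed below 0.1 FPKM in every library and only 6 were tested. Of these 6, 5 were higher and 1 was lower in libraries labelled Dif-FGSC (camera adjusted p = 0.242 for the list, and 0.6 with an estimated correlation). The lower one was Adgre1, the macrophage antigen F4/80, which fell from 20.4 ± 0.324 to 4.28 ± 0.173 FPKM (limma adjusted p = 4.19e-08).

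**Figure D1:**
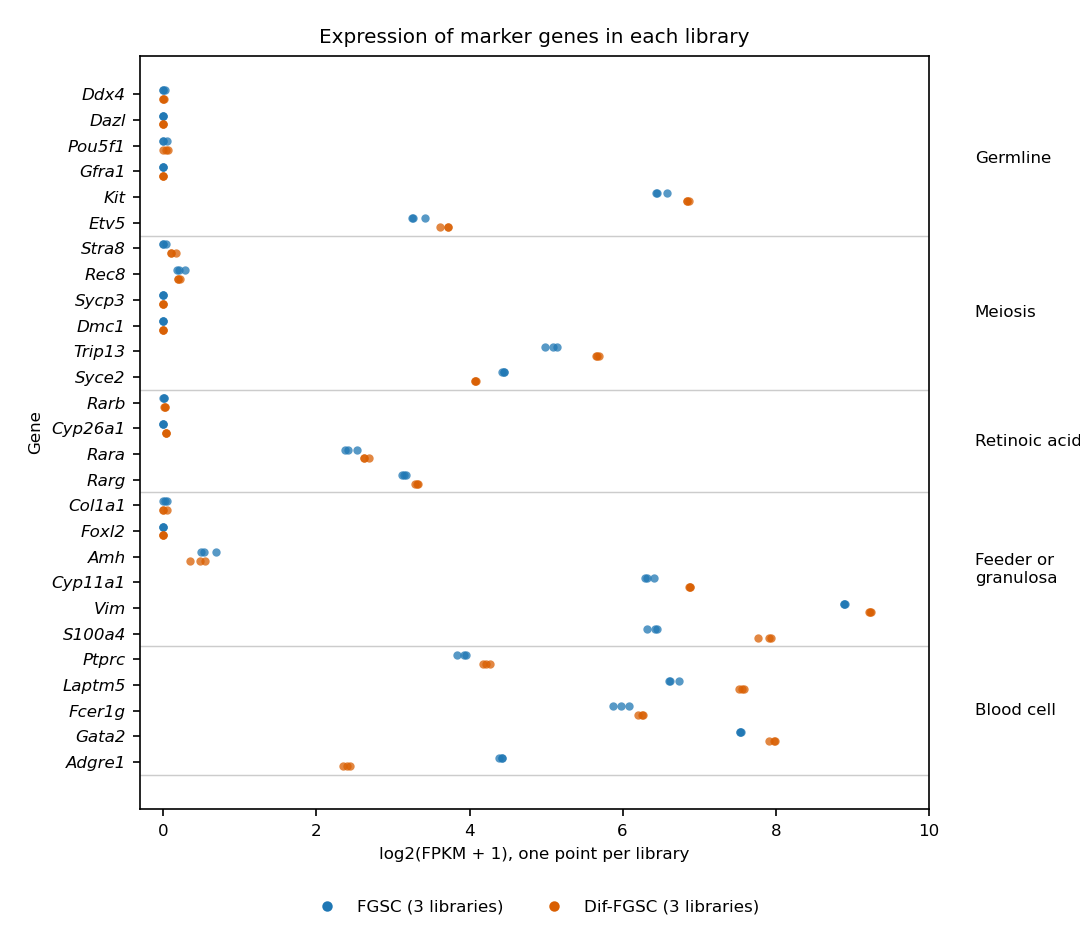
Expression of marker genes as log2(FPKM + 1), 1 point per library, with the 3 libraries labelled FGSC in blue and the 3 labelled Dif-FGSC in orange. Ddx4, Dazl, Gfra1, Sycp3, Dmc1 and Foxl2 lie at or next to 0 in all 6 libraries, while Vim, Gata2 and Laptm5 are abundant in every library.

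Markers of the feeder cells were also scarce. Col1a1, the main fibroblast collagen, did not exceed 0.034 FPKM, Foxl2, a granulosa cell transcription factor, was listed at 0 in every library, and Amh, a granulosa cell hormone, stood at 0.492 ± 0.109 FPKM in libraries labelled FGSC and 0.374 ± 0.092 in those labelled Dif-FGSC. Of 34 fibroblast and mesenchyme markers 2 were tested, and both were higher in libraries labelled Dif-FGSC. S100a4, a calcium-binding protein, rose from 83.3 ± 4.1 to 233 ± 14.4 FPKM (limma adjusted p = 8.98e-07), and Vim, the intermediate filament vimentin, from 475 ± 1.52 to 600 ± 3.5 FPKM. Of 25 granulosa markers 3 were tested and all 3 were higher. Cyp11a1, the enzyme that starts steroid synthesis, rose from 79.9 ± 3.35 to 117 ± 0.642 FPKM, Star, a cholesterol carrier of steroid-making cells, from 1.3 ± 0.0961 to 1.78 ± 0.0929, and Runx1, also a blood transcription factor, from 4.74 ± 0.533 to 5.83 ± 0.0551. The Runx1 call was lost after quantile normalization (adjusted p = 0.0732). Ptch1 and Star were the tested members of 14 theca and stroma markers, and Ptch1 rose from 4.17 ± 0.0519 to 5.11 ± 0.0886 FPKM. Egfl7, the tested member of 14 endothelial markers, fell from 5.77 ± 0.322 to 3.29 ± 0.112 FPKM. None of 19 epithelial markers and none of 39 Hox genes reached a mean of 1 FPKM.

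Many genes differed between the groups, mostly by small amounts. Of 9162 genes tested, 3343 were higher and 2622 lower in libraries labelled Dif-FGSC and 3197 were not called. Folds were counted in FPKM + 1, which understates the change of low genes. On this scale differences of at least 2-fold were found for 175 of the higher and 66 of the lower genes, and 1210 of the higher and 1179 of the lower genes changed by less than 1.2-fold. Of the 9162 genes, 70.7% had groups that did not overlap, where chance gives 10%. A change of scaling moved the balance: 3030 genes were higher and 2990 lower with median-ratio scaling, and 2789 and 3185 after quantile normalization.

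The gene with the largest listed rise was Hspa8, the constitutive heat shock chaperone, which was listed at 0 in all 3 libraries labelled FGSC and at 1451, 1455 and 1515 FPKM in those labelled Dif-FGSC. Dhdds (125.5 to 127.2 FPKM), Cbx1 (69.0 to 70.9), Luc7l3 (32.7 to 36.5), Nr3c1 (19.8 to 20.2), Ethe1 (15.5 to 16.5) and Srek1 (11.3 to 11.6) were likewise listed at 0 in every library labelled FGSC. Rnf125 was listed at 1.91, 0 and 0 FPKM in libraries labelled FGSC and at 17.4, 18.0 and 19.0 in the others. In the opposite direction Prss53 (12.8 to 15.9 FPKM in libraries labelled FGSC), Gas5 (10.3 to 16.3), Ankrd37 (8.05 to 14.1) and Kmt2a (8.14 to 10.5) were listed at 0 in every library labelled Dif-FGSC. No fold is given for these genes, since a 0 can be a failed estimate. Of the changes of at least 2-fold in FPKM + 1, 40 of the 175 rises and 17 of the 66 falls involved a gene listed at 0 in at least 1 library.

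Among genes with a value above 0 in every library and a mean of at least 5 FPKM in the higher group, the largest rise in log2(FPKM + 1) was that of Fos, an immediate early transcription factor, from 0.461 ± 0.0487 to 14.2 ± 0.398 FPKM (log2 difference 3.37 ± 0.046 SE, limma adjusted p = 7.25e-09). Egr1, another immediate early factor, rose from 0.974 ± 0.24 to 12.2 ± 0.302 FPKM. Mkln1, which encodes muskelin, rose from 0.21 ± 0.0571 to 9.25 ± 0.439 FPKM, Mchr1, a neuropeptide receptor, from 0.233 ± 0.0488 to 7.3 ± 0.558, and Ubtf, a factor of ribosomal RNA transcription, from 2.46 ± 0.192 to 21.0 ± 0.0657. Mcpt8, a granule protease of basophils and mast cells, rose from 0.597 ± 0.147 to 8.21 ± 0.925 FPKM, Cep41, a centrosomal protein, from 0.652 ± 0.0965 to 7.24 ± 0.0452, and Nt5c3b from 0.228 ± 0.162 to 5.21 ± 0.0207. The largest fall on the same scale was that of the histone gene Hist1h2af, from 38.3 ± 10.2 to 1.61 ± 0.199 FPKM, a member of a family of near-identical copies whose values are uncertain. Card9, a signalling adaptor of myeloid cells, fell from 12 ± 0.799 to 0.296 ± 0.121 FPKM, Snx10 from 7.34 ± 0.716 to 0.228 ± 0.0618, and Spint1, a protease inhibitor, from 26.4 ± 0.624 to 3.88 ± 0.391. Tph1, the rate-limiting enzyme of serotonin synthesis outside the brain, fell from 60.1 ± 18.6 to 11.1 ± 3.87 FPKM. Akr1c12 fell from 67.2 ± 3.78 to 15.9 ± 1.35 FPKM and Cd200r1, an inhibitory receptor of myeloid cells, from 18.6 ± 3.18 to 3.49 ± 0.377.

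**Figure D2:**
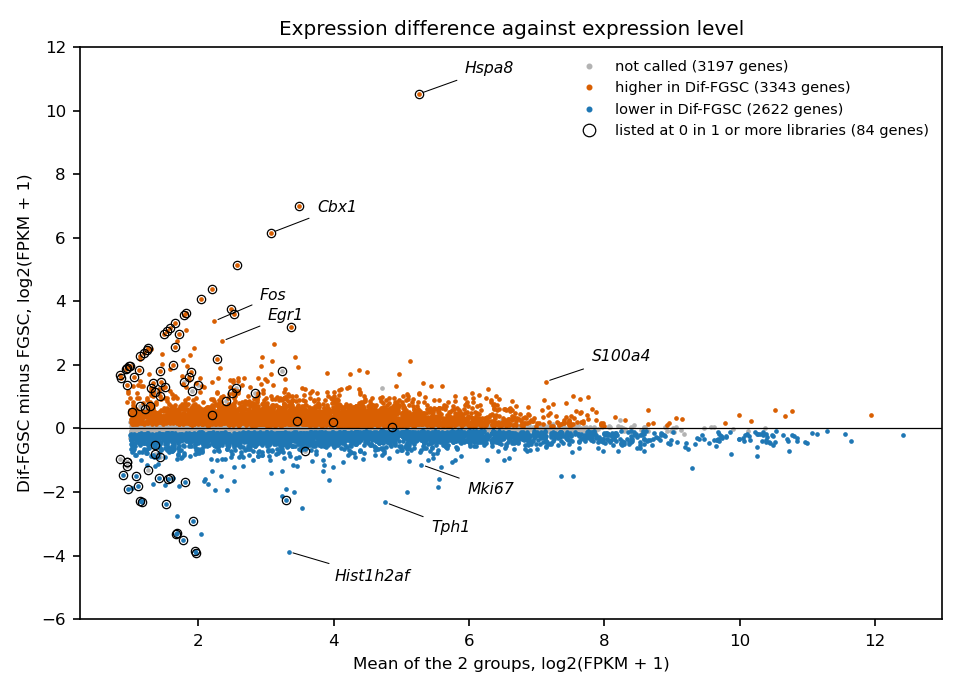
Difference between the groups (Dif-FGSC minus FGSC, log2(FPKM + 1)) against the mean of the groups, 1 point per tested gene, in orange for the 3343 higher genes and blue for the 2622 lower genes. Black circles mark the 84 tested genes listed at 0 in at least 1 library, among them Hspa8 and Cbx1 at the top.

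Genes that mark the retinoic acid response and entry into meiosis were near the floor or low. Stra8, the retinoic acid-induced gene required for entry into meiosis, was listed at 0.0249, 0 and 0 FPKM in libraries labelled FGSC and at 0.1205, 0.0693 and 0.0686 in those labelled Dif-FGSC, an estimated 1.2, 0 and 0 against 4.9, 2.5 and 2.5 fragments. Cyp26a1, the retinoic acid-degrading enzyme that retinoic acid induces, was listed at 0 in every library labelled FGSC and at about 1.0 fragment in each of the others. Rarb, a retinoic acid receptor induced by its ligand, did not exceed 0.0165 FPKM. Tgm2, a transglutaminase induced by retinoic acid and by other signals, stood above the floor in libraries labelled Dif-FGSC, at 0.0254 ± 0.0109 FPKM in libraries labelled FGSC and 1.07 ± 0.184 in the others. Rec8, the meiotic cohesin, stood at 0.168 ± 0.0471 FPKM in libraries labelled FGSC and 0.146 ± 0.0117 in those labelled Dif-FGSC, an estimated 4.9 fragments or more in each library. These 5 genes were below the filter and were not tested, and a difference of this size is near the floor of 3 fragments for Stra8 and Cyp26a1.

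Of the meiosis list, 12 of 48 genes in the table were tested, of which 3 were higher, 5 were lower and 4 were not called, with the same counts adjusted over the list alone. Trip13, a remodelling ATPase that also acts in the mitotic checkpoint, rose from 32.7 ± 1.86 to 50 ± 0.637 FPKM (log2 difference 0.60 ± 0.043 SE, limma adjusted p = 1.76e-05). Syce2, a synaptonemal complex protein, fell from 20.8 ± 0.174 to 15.9 ± 0.0438 FPKM, Psmc3ip, a recombination cofactor, from 24.4 ± 2.48 to 18.7 ± 1.29, and Brca2, which also acts in mitotic DNA repair, from 2.82 ± 0.293 to 1.88 ± 0.232. The list as a whole was not called (camera adjusted p = 0.579, and 0.616 with an estimated correlation). After quantile normalization 1 member was higher and 5 were lower.

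Of the retinoic acid list, 7 of 35 genes were tested, of which 4 were higher and none was lower, also adjusted over the list alone. Zfp703, a transcriptional corepressor, rose from 2.64 ± 0.3 to 4.06 ± 0.493 FPKM, while the receptor genes Rara, Rarg and Rxrb rose by 1.18, 1.13 and 1.14 times. The list was not called (camera adjusted p = 0.309, and 0.6 with an estimated correlation), and quantile normalization ended the calls of Rara, Rarg and Rxrb. Of the BMP list, 10 of 28 genes were tested, of which 7 were higher and 2 lower, also adjusted over the list alone (camera adjusted p = 0.213, and 0.6 with an estimated correlation). Bmpr2, a BMP receptor, rose from 3.48 ± 0.122 to 5.56 ± 0.158 FPKM, and Gata2 rose by 1.34 times. The BMP targets went both ways. Id3, Smad7 and Hey1 rose by 1.55, 1.48 and 1.57 times, and Id1 was not called. The 2 lower members were Id2, which fell from 38.6 ± 1.55 to 30.8 ± 0.914 FPKM, and Bambi, at 0.885 times.

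Of 6 tested germline genes 5 were higher and none was lower, also adjusted over the list alone (camera adjusted p = 0.118, and 0.6 with an estimated correlation). These were Kit, a receptor of germ cells and of blood cells, from 89.0 ± 5.2 to 114 ± 0.931 FPKM, Etv5, a transcription factor of the GDNF and FGF pathways, from 8.94 ± 0.67 to 11.8 ± 0.492, Upp1 from 1.23 ± 0.149 to 2.18 ± 0.159, Foxo1 from 3.18 ± 0.207 to 3.84 ± 0.254 and Itga6 from 10.4 ± 0.365 to 11.7 ± 0.4. Each of these genes is also transcribed outside the germ line. After quantile normalization 3 of these genes stayed called and the calls of Foxo1 (adjusted p = 0.154) and Itga6 were lost, and that of Foxo1 was also lost without Dif-FGSC replicate 1 (adjusted p = 0.0559). Of the piRNA list 5 of 22 genes were tested, with 2 higher and none lower (camera adjusted p = 0.565, and 0.607 with an estimated correlation), namely Tdrd3, from 3.86 ± 0.189 to 5.06 ± 0.286 FPKM, and Gpat2, from 27.3 ± 0.894 to 30.9 ± 1.01. Klf2 was the tested member of the pluripotency list and rose from 0.565 ± 0.138 to 4.71 ± 0.309 FPKM, and Kit was that of the oocyte list.

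Genes of chromatin structure were expressed in both groups and changed in both directions. Ctcf, the insulator protein at loop anchors, rose from 25.6 ± 0.852 to 29.5 ± 0.153 FPKM (log2 difference 0.20 ± 0.033 SE, limma adjusted p = 0.00127). Rad21, a subunit of cohesin, fell from 109 ± 1.12 to 96.4 ± 1.67 FPKM. Of 35 tested architecture genes 8 were higher, 17 lower and 10 not called, and 9 were higher and 18 lower adjusted over the list alone. Smc4, a condensin subunit, fell from 38.0 ± 4.53 to 19.5 ± 1.15 FPKM, Smc3, a cohesin subunit, from 52.5 ± 3.63 to 35.0 ± 0.699, Nipbl, the cohesin loader, from 5.76 ± 0.533 to 3.87 ± 0.156, and Sgo2a, a protector of centromeric cohesin, from 7.53 ± 0.595 to 4.89 ± 0.169. The list missed the threshold (camera adjusted p = 0.0708, and 0.6 with an estimated correlation), and passed it with median-ratio scaling (0.049) and without FGSC replicate 2 (0.0318), within a range of 0.0318 to 0.6 over all alternatives tested with camera.

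Of 44 tested chromatin modifiers 24 were higher and 5 lower, also adjusted over the list alone (camera adjusted p = 0.118, and 0.6 with an estimated correlation). The 5 lower members include Kmt2a, which was listed at 0 in every library labelled Dif-FGSC and may be a failed estimate. Kdm5b, a histone H3K4 demethylase, rose from 9.85 ± 0.383 to 22.9 ± 0.262 FPKM (limma adjusted p = 5.33e-07). Tet3, an oxidase of methylated cytosine, rose from 2.6 ± 0.0988 to 4.49 ± 0.118 FPKM and Crebbp, a histone acetyltransferase, from 1.49 ± 0.14 to 2.81 ± 0.222, while Hdac2, a histone deacetylase, fell from 71.0 ± 2.19 to 55.0 ± 0.128. After quantile normalization 18 members were higher and 10 lower.

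Most tested targets of the ERK and STAT3 pathways were higher in libraries labelled Dif-FGSC. Of 19 tested members 14 were higher, 3 lower and 2 not called, also adjusted over the list alone, with a median log2 difference of 0.46 (camera adjusted p = 0.00433, and 0.6 with an estimated correlation). Besides Fos and Egr1, Junb, a partner of Fos, rose from 23.4 ± 0.661 to 64.5 ± 2.91 FPKM, and Fosl1, a member of the Fos family, from 3.67 ± 0.933 to 11.3 ± 0.84. Dusp5, an ERK phosphatase, rose from 8.88 ± 0.568 to 17.8 ± 1.15 FPKM. Etv4, Spry1 and Dusp6 were the 3 lower members, at 0.784, 0.798 and 0.796 times the level in libraries labelled FGSC, while Spry4, Spred2, Etv5 and Spred1 rose by 2.04, 1.4, 1.32 and 1.28 times.

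Genes of cholesterol synthesis were lower in libraries labelled Dif-FGSC, and FGSC replicate 3 stood apart from the other replicates of its group. Of 22 tested members 17 were lower and none higher, also adjusted over the list alone, with a median log2 difference of -0.62 (camera adjusted p = 0.00433, and 0.6 with an estimated correlation). Msmo1, a sterol oxidase, was listed at 53.5, 54.7 and 114.9 FPKM in libraries labelled FGSC and at 29.3, 29.2 and 29.6 in the others (limma adjusted p = 0.00456). Fdft1, which makes squalene, was listed at 10.4, 10.2 and 23.3 against 6.12, 6.36 and 7.18 FPKM, and its call was lost with no filter (adjusted p = 0.0531), with a robust variance model (0.0698) and without Dif-FGSC replicate 1 (0.0517), at log2 differences of -0.95, -0.95 and -0.91 against -0.95. The mean log2(FPKM + 1) over the list was 4.29, 4.30 and 5.02 in libraries labelled FGSC and 3.96, 3.96 and 3.95 in the others. Without FGSC replicate 3 the same number of members, 17, was lower and 1 was higher, the median was -0.41 and the camera adjusted p was 4.16e-05. Only 10 members were called without Dif-FGSC replicate 1 and 9 without Dif-FGSC replicate 3, at medians of -0.63 and -0.62, and fry, a test of the list by itself, did not call it (adjusted p = 0.114).

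Genes of glycolysis and the hypoxia response were lower on balance. Of 26 tested members 16 were lower and 5 higher, also adjusted over the list alone, with a median log2 difference of -0.20 (camera adjusted p = 0.00643, and 0.6 with an estimated correlation). The 16 lower members include Ankrd37, which was listed at 0 in every library labelled Dif-FGSC and may be a failed estimate. Bnip3, a hypoxia-induced mitophagy receptor, fell from 77.2 ± 6.96 to 38.2 ± 1.77 FPKM, Pgk1, a glycolytic kinase, from 456 ± 10.7 to 324 ± 4.1, and Eno1, the glycolytic enolase, from 948 ± 15.8 to 722 ± 12.2. Hk1, the hexokinase that starts glycolysis, rose from 50.3 ± 0.712 to 62.2 ± 0.5 FPKM. After quantile normalization the list was not called (camera adjusted p = 0.11, within a range of 0.00205 to 0.6 over all alternatives tested with camera), while 15 members were lower and 3 higher at a median of -0.14.

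Mitotic genes were lower on balance in libraries labelled Dif-FGSC. Of 40 tested members 23 were lower, 8 higher and 9 not called, also adjusted over the list alone, with a median log2 difference of -0.14 (camera adjusted p = 0.00643, and 0.6 with an estimated correlation). Mki67, the proliferation antigen, fell from 57.6 ± 8.42 to 25.4 ± 0.358 FPKM and Cenpf, a kinetochore protein, from 15.7 ± 2.38 to 6.25 ± 0.315 (limma adjusted p = 2.64e-05 and 3.54e-05). Among the higher members were Foxm1, a transcription factor of the G2 phase, from 20.5 ± 0.446 to 28.4 ± 0.134 FPKM, and E2f1, a transcription factor of S phase entry, from 5.78 ± 0.0995 to 8.6 ± 0.485. After quantile normalization the list was not called (camera adjusted p = 0.11, within a range of 0.00275 to 0.6 over all alternatives tested with camera), while 23 members were lower and 9 higher at a median of -0.13.

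Cell cycle inhibitors and p53 targets went both ways, with 9 of 18 tested members higher and 7 lower, also adjusted over the list alone (camera adjusted p = 0.579, and 0.799 with an estimated correlation). Cdkn1a, the p53-induced inhibitor p21, rose from 25.8 ± 2.14 to 46.1 ± 0.491 FPKM and Zmat3, another p53 target, from 2.99 ± 0.171 to 7.98 ± 0.255. Cdkn1b, the inhibitor p27, fell from 18.5 ± 0.888 to 12.8 ± 0.663 FPKM. Of 21 tested stress and unfolded protein genes 7 were higher and 9 lower, and 8 and 10 adjusted over the list alone (camera adjusted p = 0.565, and 0.6 with an estimated correlation). Ddit3, the stress factor CHOP, was listed at 0, 18.2 and 22 FPKM in libraries labelled FGSC and at 0 in all the others. Its call (limma adjusted p = 0.0434) was lost under 8 of the alternatives, in 6 of them with the estimated difference unchanged. Chac1, which degrades glutathione, fell from 7.61 ± 2.16 to 1.98 ± 0.399 FPKM. Hmox1, a heme-degrading enzyme, rose from 29.8 ± 2.79 to 76.0 ± 0.81 FPKM and Gclm, an enzyme of glutathione synthesis, from 58.6 ± 5.01 to 119 ± 2.11, while Nqo1, a quinone reductase, fell from 6.1 ± 0.471 to 4.77 ± 0.586. Of 11 tested interferon genes 4 were higher and 4 lower (camera adjusted p = 0.579, and 0.616 with an estimated correlation). Stat2, a transcription factor of the interferon response, fell from 6.46 ± 1.27 to 3.24 ± 0.132 FPKM and Usp18, an inhibitor of that response, from 3.02 ± 0.488 to 1.63 ± 0.489.

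**Figure D3:**
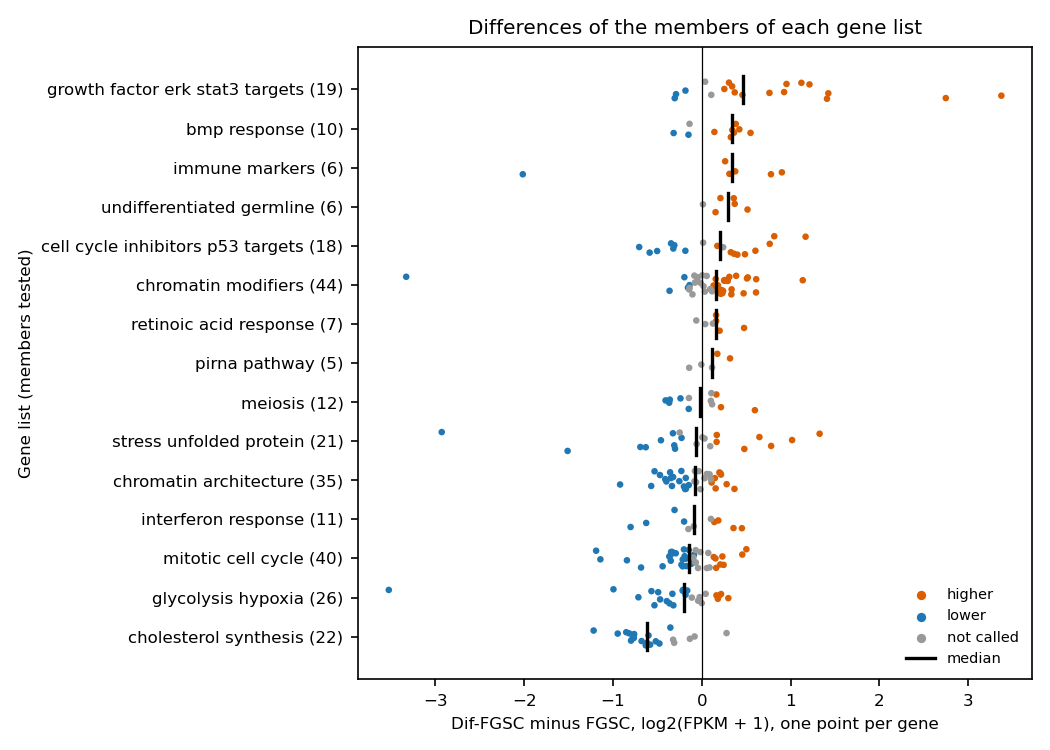
Difference (Dif-FGSC minus FGSC, log2(FPKM + 1)) of each tested member of the 15 tested lists, 1 point per gene, in orange where called higher, blue where called lower and grey where not called, with black bars at the medians. The medians run from 0.46 for the ERK and STAT3 targets to -0.62 for cholesterol synthesis.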

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

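With at least 2-fold in FPKM + 1 required, 175 genes were higher and 66 lower in place of 3343 and 2622. Under the other alternatives the counts of calls stayed within 1.5 times, and leaving out 1 library gave 2984 to 3401 higher and 2317 to 2565 lower genes. Leaving out genes listed at 0, a choice made after the data were seen, gave 3326 and 2644. Among the tested genes named by the rules, which leave out Itga6, 1155 of 1172 values under alternatives stayed called in the same direction. None turned, and 7 genes lost a call at least once (Ddit3, Fdft1, Foxo1, Rara, Rarg, Rxrb and Runx1). Most tested genes named by the rules were picked because they were called in the main fit with large differences. That choice raises the share that stayed called, which does not measure how stable the other calls are. Of 282 list values, 262 kept direction and side of the threshold. All 4 called lists missed it with an estimated correlation (adjusted p = 0.6 for ERK and STAT3 targets, mitosis, cholesterol synthesis and glycolysis). Quantile normalization ended the calls of mitosis and glycolysis (0.11 each), and fry that of cholesterol synthesis (0.114). Fry, which does not compare a list with other genes, called germline (0.00146), retinoic acid (0.00723), BMP (0.00118), architecture (0.00826), modifiers (0.0011), piRNA (0.00347) and p53 targets (0.00674). The direction turned with fry for immune (0.222, down) and stress genes (0.025, up), with a filter at 5 FPKM for BMP (0.786, down) and with no filter for interferon genes (0.588, up), and the cause was not tested. Architecture genes passed with median-ratio scaling (0.049) and ranged from 0.0318 to 0.0937 when 1 library was left out. The same range was 0.00273 to 0.00826 for ERK and STAT3 targets, 0.00289 to 0.0103 for mitosis, 0.00273 to 0.0102 for glycolysis and 4.16e-05 to 0.00826 for cholesterol synthesis. The lists for pluripotency, oocyte, granulosa, fibroblast, theca, epithelial, endothelial and Hox genes had too few tested members for a list test under the main filter. With no filter they had enough members and were tested with camera, but those results are not reported here. The adjusted p-values of the other lists with no filter were therefore adjusted over these lists too.

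The shared replicate numbers were not taken as pairs, since nothing in the labels says that they mark a shared culture or day. Deviations from the group means correlated at 0.13, 0.01 and 0.17 between libraries of the same number. Between libraries of different numbers they correlated at -0.22 to 0.11. Of 6 libraries, 4 correlated best with their own number, so an effect shared by libraries of the same number is not excluded. A block by replicate number gave 3241 higher and 2557 lower genes and changed no list or named gene call. Depth limits what can be said of genes below 0.055 to 0.086 FPKM, the value of 3 fragments on a transcript of 2000 bp.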

Other observations

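The tests of the gene lists in the next paragraph, of misplaced symbols, feeder fibroblasts, granulosa cells and mast cells, and of other splits of the libraries were chosen only after the result was seen.

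Ribosomal protein genes, a group not described above, were lower in libraries labelled Dif-FGSC: of 79 tested, 67 were lower and 2 higher, with a median log2 difference of -0.29 (camera adjusted p = 3.88e-14, and 0.0576 with an estimated correlation), and after quantile normalization 39 were lower and 8 higher with a median of -0.10 (camera adjusted p = 0.0088, and 0.142 with an estimated correlation). Rpl3, a protein of the large subunit, fell from 919 ± 27.3 to 717 ± 6.58 FPKM, and ribosomal protein genes took 22.3% to 22.7% of all FPKM in libraries labelled FGSC against 19.2% to 19.4% in the others. Of 78 genes of oxidative phosphorylation 49 were lower and 6 higher (camera adjusted p = 3.15e-07, and 0.0576 with an estimated correlation), and after quantile normalization 42 were lower and 12 higher (camera adjusted p = 0.0088, and 0.345 with an estimated correlation). Of 16 immediate early genes 11 were higher and 1 lower (camera adjusted p = 0.000482, and 0.0576 with an estimated correlation), among them Fosb, from 0.0409 ± 0.0137 to 4.85 ± 0.23 FPKM, and Fosl2, from 6.62 ± 0.569 to 13.2 ± 0.433. Of 16 genes of blood cells in general 7 were higher and 2 lower (camera adjusted p = 0.305, and 0.574 with an estimated correlation), and of 13 mast cell genes 9 were higher and 1 lower (camera adjusted p = 0.0212, and 0.243 with an estimated correlation). Of 14 granule protease genes in the table, which had no list test, 5 were tested, of which 3 were higher, 1 lower and 1 not called: Mcpt8 rose, Gzmb rose from 2.53 ± 0.267 to 15.9 ± 0.576 FPKM and Mcpt2 from 0.371 ± 0.31 to 4.57 ± 1.02, Ctsg fell from 6.17 ± 0.0478 to 3.35 ± 0.253, and Cpa3, at 288 ± 19.0 and 301 ± 10.5, was not called. Xist, the RNA of the inactive X chromosome, did not exceed 0.0023 FPKM in any library, and the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were listed at 0 in all 6, so these genes leave the sex of the cells open. Trap1a, a tumour antigen originally cloned from a mastocytoma line and also transcribed in testis, stood at 307 ± 5.73 and 256 ± 10.3 FPKM.

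Most markers of germ cells, meiosis and pluripotency were at or near 0 in every library while genes of blood cells were abundant. Failed estimates as the cause for the markers as a set are argued against by the 0.0% of 116 broadly used genes listed at 0 in all libraries, against 43 of 98 markers (43.9%, Fisher's exact test, two-sided p = 4.3e-18). Outside the 116, Hspa8 and Rpl30 were listed at 0 in some libraries though not in all, so a failed estimate of a single marker is not excluded. Symbols out of register with the values are argued against by 90.6% of 85 ribosomal protein genes lying in the top 10% of genes. RNA of feeder fibroblasts or of granulosa cells in place of germ cells is argued against by 5.9% and 12% of their marker lists reaching 1 FPKM. A candidate explanation, as a hypothesis, is that the RNA came from cells of the mast cell lineage: of list genes not seen before the lists were written, 6 of 17 mast cell genes but 2 of 46 genes of 6 other blood lineages reached 5 FPKM (Fisher's exact test, two-sided p = 0.0035), Cpa3 among the 6. The other lineages were macrophage, neutrophil, T cell, B cell, erythroid and megakaryocyte. Basophils and blood progenitors had no list, so the test cannot tell mast cells from these. With genes seen before, such as Gata2, Cyp11a1 and Kit, the counts at 5 FPKM or more were 11 of 23 and 3 of 61. The mast cell genes below 5 FPKM go against the hypothesis, and only 13 of the 23 reached a mean of 1 FPKM. Among the low ones, Tpsb2 and Mrgprb2 were listed at 0 in every library. Fcer1a (at most 0.0431 FPKM), Tpsab1 (0.0212), Mcpt1 (0.0888), Hdc (0.149), Ms4a2 (0.174) and Mcpt4 (0.309) were also low. Whether such cells replaced the named culture, arose in it or entered through another sample was not tested and stays open.

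Genes listed at 0 in all libraries of 1 group and at a mean of 5 FPKM or more in the other numbered 17, of which 12 were at 0 in libraries labelled FGSC and 5 in those labelled Dif-FGSC. A candidate explanation is an estimate lost to, or gained from, another gene at the same place: 13 of the 17 (76.5%) overlap another RefSeq gene, against 43.5% of 6660 other genes at 5 FPKM or more (Fisher's exact test, two-sided p = 0.012). Transcription switched off in 1 group cannot be told apart from this. Of 31 genes below 5% of the other group's mean, 21 (67.7%, exact 95% interval 48.6% to 83.3%) were at exactly 0 in all 3 libraries rather than at a few fragments, and the interval includes 50%. The 17 genes are among the 31 by definition, so this share cannot decide between the explanations. A further 22 genes were listed at 0 in some libraries of a group and at a mean of 5 FPKM or more in the rest, Ddit3 and Rpl30 among them. Rpl30, a ribosomal protein gene, was listed at 38.9, 0 and 42.7 FPKM in libraries labelled FGSC and at 0, 34.8 and 51.7 in the others. A listed 0 thus also occurred without a difference between the groups.

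Of the 10 splits of the 6 libraries into groups of 3, the real one called 5965 genes and the highest of the others called 1. Only 1 split called as many as the real one, the real one itself, and with 10 splits a share under 0.05 cannot be reached. Every other split also mixed libraries of both groups on each side. Any difference between the groups then widens the spread within a side and lowers the calls, so the contrast adds nothing to the main fit.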
